A study of Homo sapiens with 4 samples.

How the data were processed

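RNA of SKOV3ip1 ovarian cancer cells was hybridised to 4 Illumina expression arrays, 2 of cells kept alone and 2 of cells kept for 16 h with freshly isolated human omental adipocytes. Per the labels' protocols, cells were grown in medium with 10% serum and then held in medium with 0.1% albumin, the adipocytes were rinsed off before extraction, and biotin-labelled cRNA was hybridised. The group of each array was taken from the co-culture label. The values used are the probe intensities that the authors deposited in a table of all 4 arrays, with 47319 probes. Per the submitters' processing notes the tool was GenomeStudio 2011.1, and its background and normalization settings are not given in the sources used here.

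The scale of these intensities was found from the values. They are linear, since they run from -15 to 18562.2, and 26.9% are below 0, so a background had been subtracted. The sorted values of the 4 arrays differ by at most 0.1 and each array has a median of 4.2, so they had been quantile-normalized, which forces the arrays to 1 shared distribution and hides any difference in total signal between the groups. The direction follows from the array labels, and no centring per gene had been done. A table of unnormalized intensities with detection p-values has 8 columns whose names match no sample, so it was not used here. The design fixed before the data were examined had assumed such a table (background correction and normalization with neqc, a filter on detection p), with the deposited normalization to be kept where the values were already normalized, and this was done.

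Intensities under 16 were set to 16, log2 was taken, and probes above 16 on at least 2 of the 4 arrays were kept (14723 probes). Gene names came from the platform annotation given with the data, in which 30111 probes have 1 symbol, 8 have several and 17200 are unnamed here. Of the probes with 1 symbol, 30072 were found by Entrez gene number in the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. No genome build is named for the probes, so no coordinates are given. For each gene the kept probe with the highest mean log2 intensity was used, which gave 9640 genes from 12207 named probes. Of 2166 genes with several kept probes, 14 had probes called in opposite directions, and none of these is named here.

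The contrast was co-culture minus cells alone. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariates. The residual degrees of freedom were 2 and the prior added 3.00, around a prior SD of 0.107 in log2. Every SE given is the moderated one of this fit, so it also rests on the prior. The median SD between arrays of a group was 0.080 for cells alone and 0.082 for co-culture. The floor gives genes at 16 a spread of 0 within a group, so their errors rest on the other group and on the prior. A gene whose probes were all at or under 16 on both arrays of a group has only a bound there, and its fold against the floor is written as at least that size. This holds for 169 higher and 151 lower genes. Folds are 2 to the power of the log2 change.

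Before the data were examined, 22 gene lists and 7 lists of cell type markers were fixed, together with the rule for named genes. The rule takes the 6 largest rises and 6 largest falls among genes past the threshold with groups that do not overlap and with an established symbol, the 2 members of each gene list with the smallest adjusted p (or 1 where none passed), the brightest tested member and any changed member of each marker list, and FABP4 and CD36. It named 68 tested genes. The lists were tested with camera (preset inter-gene correlation of 0.01, at least 3 tested genes, Benjamini-Hochberg over 27 lists), and again with an estimated correlation and with fry. Further lists and gene families were defined after the data were seen and appear only among the additional observations. Figures were drawn with matplotlib 3.10.9.

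The fit, the choice of probes and the list test were tested on 10 simulated sets of 4 arrays for this comparison, built from the measured probe means, with 200 changed genes each and a median of 9552 genes tested. A log2 change of 2 was called for 97.9% of genes, of 1 for 77.0% and of 0.5 for 7.58%, and falls of these sizes were called for 97.9%, 75.9% and 6.97%. Of all calls, 5.37% were of unchanged genes. A list of 30 genes raised by a log2 change of 1 was called in all 10 sets, and 0 of 261 tests of unshifted lists passed. The simulated noise was drawn independently for each probe, so the list test was not checked under correlation between genes. Changed genes were drawn only from those with a mean log2 intensity more than 1 above the floor, so recovery near the floor was not checked. Noise of probes with a mean above 16 followed the prior variance fitted by limma, so departures from that model were not checked. Each set changed far fewer genes than the 3827 called in the data, so these rates need not hold there.

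Alternatives were no filter, all probes tested singly, the mean of a gene's probes, an intensity trend with a robust prior, a 2-fold minimum, a replicate block and each array left out. Added after the data were seen were floors of 8 and 32, a filter above 16 on all 4 arrays, and log2 of intensity plus 50, the last also with each array left out. Slide and scan date are not given in the sources used here, so no block for them was fitted.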

Results

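Gene expression was measured on Illumina expression BeadChips, glass arrays of bead-bound probes read by fluorescence, in SKOV3ip1 cells, an established human ovarian cancer line. The 2 groups were cells kept alone (2 arrays) and cells kept with freshly isolated human primary omental adipocytes, the fat cells of the omentum (2 arrays). Both groups spent 16 h in medium with 0.1% bovine serum albumin, and the adipocytes were washed off before RNA was extracted from the remaining cells. Each array gave an intensity for 47319 probes, of which between 14230 and 14232 per array lay above an intensity of 16. After the filter on dim probes, 9640 genes were tested. Nothing in the labels says that the arrays of a group came from separate cultures or donors. Each limma p-value therefore rests on the spread between these arrays, which may be technical, and on a prior pooled over genes. Camera p-values with the preset correlation set a list against the other tested genes rather than measuring that spread. The number of arrays limits the precision. Pearson's r of log2 intensity across genes, which are not independent replicates, was 0.994 between the arrays of each group and from 0.946 to 0.948 between arrays of different groups.

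The comparison asked which transcripts of the cancer cells differed after contact with adipocytes. Cytokine and interferon-response genes rose most: the cytokine IL6 was at least 101-fold higher in co-culture, and the antiviral enzyme gene OAS2 at least 82.7-fold. Genes of cell division and of glycolysis also rose, while genes of cholesterol and fatty acid synthesis fell. In all, 3827 genes changed (39.7% of those tested, limma, adjusted p under 0.05), of which 1776 were higher and 2051 lower in co-culture. A change of at least 2-fold was seen in 477 higher and 379 lower genes, and of at least 8-fold in 34 higher and 7 lower genes. Both co-culture arrays lay beyond both arrays of cells alone for 7044 genes (73.1%), where chance gives 33.3%.

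With any 1 of the 4 arrays left out, 1 group held a single array and every limma call was lost. All 3827 genes kept their direction, which was fixed in advance, since their groups did not overlap. With no filter on dim probes 641 genes were called among 20044. An exact permutation test of single genes could not pass the threshold, since 2 arrays against 2 allow no p below 0.333.

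**Figure D1:**
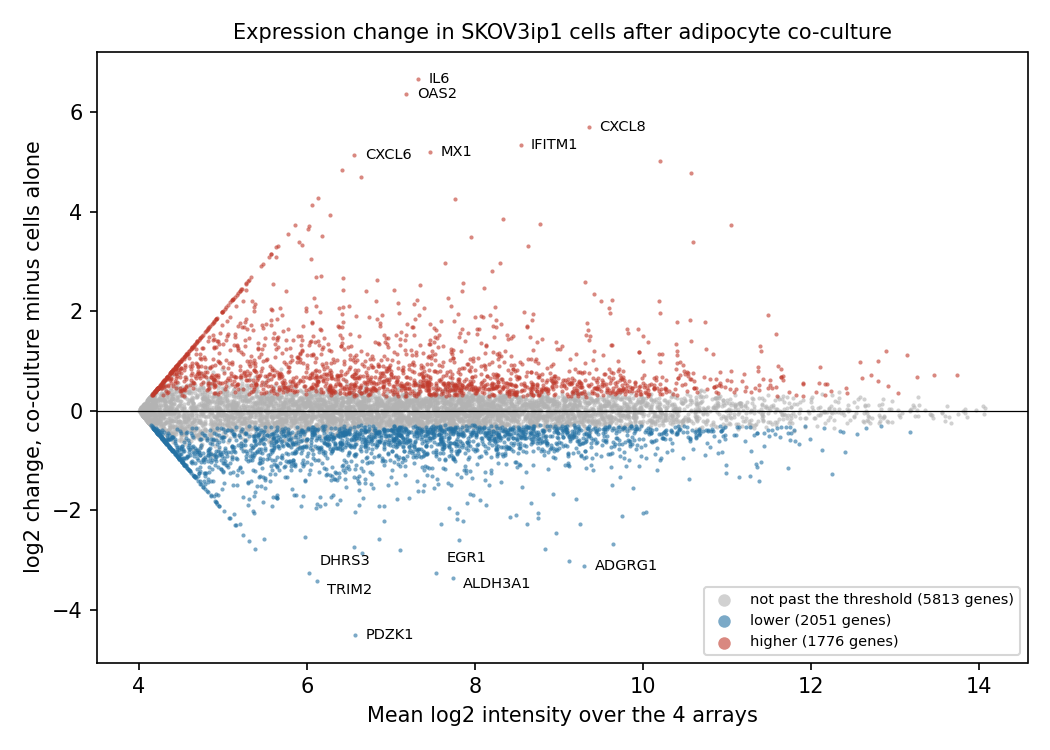
Each point is 1 of the 9640 tested genes, with its mean log2 intensity over the 4 arrays on the horizontal axis and its log2 change (co-culture minus cells alone) on the vertical axis, coloured by whether it was higher, lower or not past the threshold. The 1776 higher genes reach a log2 change of at least 6.66 (IL6), the 2051 lower genes reach -4.50 (PDZK1), and the slanted edges on the left are genes whose intensity in a group was set to the floor of 16.

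The 6 largest rises were those of IL6, OAS2, the neutrophil chemokine CXCL8, the interferon-induced membrane protein gene IFITM1, the antiviral GTPase gene MX1 and the chemokine CXCL6. CXCL8 rose 51.8-fold (log2 change 5.69 ± 0.10, moderated SE, n = 2 arrays per group). IFITM1 rose 40.5-fold (5.34 ± 0.08) and MX1 36.9-fold (5.20 ± 0.12). CXCL6 was not above an intensity of 16 in cells alone and was at least 35.1-fold higher in co-culture. The adjusted p of these 6 genes lay between 3.42e-05 and 8.98e-05. The 6 largest falls were those of the scaffold protein gene PDZK1, the ubiquitin ligase gene TRIM2, the aldehyde dehydrogenase gene ALDH3A1, the retinaldehyde reductase gene DHRS3, the immediate early transcription factor gene EGR1 and the adhesion receptor gene ADGRG1. PDZK1 was 22.7-fold lower in co-culture (log2 change -4.50 ± 0.13, SE), TRIM2 10.8-fold (-3.43 ± 0.09) and ALDH3A1 10.3-fold (-3.36 ± 0.10). DHRS3 was 9.65-fold lower (-3.27 ± 0.13), EGR1 9.58-fold (-3.26 ± 0.23) and ADGRG1 8.70-fold (-3.12 ± 0.09). Their adjusted p lay between 1.37e-04 and 9.37e-04.

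**Figure D2:**
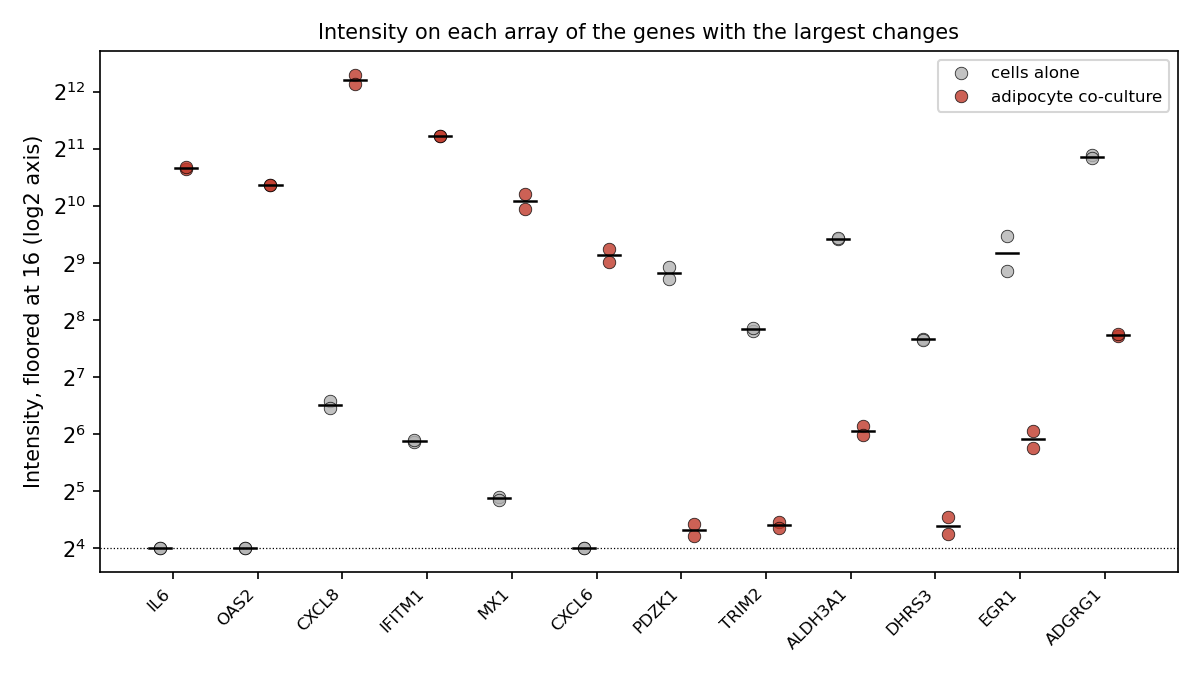
Intensity of the 6 genes with the largest rises and the 6 with the largest falls on each array, floored at 16 (dotted line) on a log2 axis, with a point per array and a bar at the mean of the log2 values of each group (n = 2). For each gene the points of co-culture lie apart from those of cells alone, which the rule that chose these genes required. IL6 lies at 1603 and 1630 in co-culture against the floor in cells alone.

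Inflammatory and interferon-response genes rose. All 24 tested genes of the NF-kB and inflammatory cytokine list were higher, with a median log2 change of 2.35 (camera adjusted p = 8.65e-18; adjusted p = 0.136 with an estimated correlation). Its named members were IL6, CXCL8 and CXCL6, given above, and CCL20. CCL20, a chemokine for dendritic cells and lymphocytes, was at least 28.4-fold higher in co-culture. All 31 tested genes of the interferon response list were higher, with a median log2 change of 2.62 (camera adjusted p = 1.09e-21; adjusted p = 0.136 with an estimated correlation). All 12 tested genes of the JAK-STAT3 and acute phase list were higher too, with a median log2 change of 1.11 (camera adjusted p = 7.22e-08; adjusted p = 0.174 with an estimated correlation). In that list the acute phase protein gene SAA1 was at least 13.3-fold higher and the oncostatin M receptor gene OSMR at least 3.01-fold. Members not above the filter were not tested, 4, 1 and 10 in these 3 lists, and adjusted over the list alone the counts stayed at 24, 31 and 12. Beside these lists, 5 of 8 tested fibroblast and preadipocyte markers were higher in co-culture. Among them the proteoglycan gene DCN had an intensity of 120 and 155 there on 1 probe, with its other probes under 16. Of 4 tested macrophage and monocyte markers CD14 was at least 1.70-fold and CD68 1.59-fold higher (camera adjusted p = 0.0833). The other CD14 probe read under 16 on every array.

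Genes of cell division rose together. Of 31 tested S and M phase genes, 29 were higher, none was lower and 2 did not pass (30 higher adjusted over the list alone). Their median log2 change was 1.63 (camera adjusted p = 2.45e-16; adjusted p = 0.174 with an estimated correlation). The ubiquitin-conjugating enzyme gene UBE2C, which acts in mitotic exit, rose 4.63-fold (log2 change 2.21 ± 0.08, SE), and the spindle checkpoint kinase gene BUB1 rose 5.26-fold (2.40 ± 0.09). Of the 12 tested p53 target genes, 1 was higher and 4 were lower, with the same counts adjusted over the list alone. The list did not shift by camera (adjusted p = 0.612) but passed by fry (adjusted p = 0.0374). Within it the cell cycle inhibitor gene CDKN1A was 3.20-fold higher, and TP53INP1, a p53-induced stress gene, was 3.88-fold lower.

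Sterol and fatty acid synthesis genes fell. Of 18 tested genes of cholesterol synthesis and uptake, 16 were lower, none was higher and 2 did not pass, with a median log2 change of -1.24 (camera adjusted p = 2.38e-08; adjusted p = 0.174 with an estimated correlation). The sterol reductase gene TM7SF2 was 6.88-fold lower (log2 change -2.78 ± 0.08, SE) and DHCR7, which encodes the last enzyme of the Kandutsch-Russell pathway to cholesterol, was 4.46-fold lower (-2.16 ± 0.09). Of 13 tested genes of fatty acid synthesis and desaturation, 11 were lower and 2 did not pass, with a median log2 change of -1.08 (camera adjusted p = 9.98e-06; adjusted p = 0.174 with an estimated correlation). The acetyl-CoA synthetase gene ACSS2 was 6.44-fold lower (-2.69 ± 0.10) and the fatty acid elongase gene ELOVL6 2.72-fold (-1.45 ± 0.09). Adjusted over the list alone, these counts stayed at 16 and 11 lower. Of 6 tested genes of sterol efflux and other targets of the sterol sensor LXR, none was higher, 2 were lower and 4 did not pass (5 lower adjusted over the list alone). Its median log2 change was -0.43 (camera adjusted p = 0.0439; adjusted p = 0.253 with an estimated correlation), and the list passed under 8 of 19 other settings. The cholesterol exporter gene ABCA1 was 1.79-fold lower (-0.84 ± 0.09) and the ubiquitin ligase gene MYLIP, whose product degrades the LDL receptor, 1.41-fold (-0.49 ± 0.10).

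FABP4 and CD36, lipid carriers studied in the uptake of fatty acids from adipocytes, stayed below the filter. The FABP4 probe read 3.9 and 2.6 in cells alone and 12.8 and 13.9 in co-culture, all under the floor of 16, so no fold is given here. The 3 CD36 probes read between -10.7 and 5.2 on every array. The list of fatty acid uptake, binding and lipid droplet genes split, with 7 of 16 tested members higher, 7 lower and 2 not past the threshold, and the same counts adjusted over the list alone. It did not shift (camera adjusted p = 0.791), and its median (-0.04) and mean (0.04) differ in sign. The phosphatidate phosphatase gene LPIN1 was 4.15-fold lower (log2 change -2.05 ± 0.09, SE) and FABP3, a fatty acid binding protein gene, 3.55-fold (-1.83 ± 0.10). PLIN2, the coat protein of lipid droplets, was higher by a log2 change of 2.63 ± 0.15, and was chosen for mention after its value was seen. Of 19 tested genes of fatty acid oxidation and PPAR targets, 3 were higher, 9 lower and 7 not past the threshold, with 12 lower adjusted over the list alone. Their median log2 change was -0.33 (camera adjusted p = 0.0484; adjusted p = 0.253 with an estimated correlation), and the list passed under 7 of 19 other settings. The mitochondrial carrier gene UCP2 was 6.03-fold lower (-2.59 ± 0.10). ANGPTL4, which encodes an inhibitor of lipoprotein lipase, was 10.5-fold higher (3.39 ± 0.15), from intensities near the floor in cells alone (16.6 and 20.5).

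Hypoxia and glycolysis genes were higher for 23 of 25 tested members, with none lower (24 higher and 1 lower adjusted over the list alone). The median log2 change was 0.74 (camera adjusted p = 6.44e-10; adjusted p = 0.174 with an estimated correlation). The vasodilator peptide gene ADM rose 5.05-fold (2.34 ± 0.10, SE) and NDRG1, a hypoxia-induced stress gene, rose 4.19-fold (2.07 ± 0.09). All 6 tested metallothioneins, which bind zinc and copper, were higher, with a median log2 change of 1.83 (camera adjusted p = 1.44e-05; adjusted p = 0.174 with an estimated correlation). Of these, MT1E rose 8.53-fold, from a level above 16 on 1 of the 2 arrays of cells alone, and MT1G was at least 4.75-fold higher. Of 14 tested genes of ERK pathway feedback, 12 were higher and 1 lower, with a median log2 change of 1.02 (camera adjusted p = 2.21e-05; adjusted p = 0.174 with an estimated correlation). The transcription factor gene ETV5 rose 2.36-fold, and the ephrin receptor gene EPHA4 was at least 2.48-fold lower. Adjusted over the list alone, the counts of these last 2 lists did not differ.

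Several stress and signalling lists rose with members on both sides. Of 23 tested ATF4 and amino acid stress genes, 14 were higher and 3 lower, with a median log2 change of 0.55 (camera adjusted p = 0.00171; adjusted p = 0.174 with an estimated correlation). The mitochondrial folate enzyme gene MTHFD2 rose 2.11-fold and the transcription factor gene CEBPB 1.97-fold. Of 12 tested glucocorticoid-responsive genes, 8 were higher and 2 lower, with a median log2 change of 0.82 (camera adjusted p = 0.00171; adjusted p = 0.273 with an estimated correlation), but TSC22D3, a direct target of the glucocorticoid receptor, was 4.29-fold lower. Of 14 tested immediate early genes, 7 were higher and 2 lower, with a median log2 change of 0.50 (camera adjusted p = 0.0112; adjusted p = 0.215 with an estimated correlation). FOSL1, which encodes a subunit of AP-1, rose 10.0-fold, from intensities near the floor in cells alone (22.5 and 16.9). MYC rose 2.83-fold, while EGR1 fell. The counts of these 3 lists were the same adjusted over the list alone.

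Of 21 tested mesenchymal and matrix genes, 10 were higher, 2 lower and 9 not past the threshold (10 higher and 4 lower adjusted over the list alone). Their median log2 change was 0.24 (camera adjusted p = 0.00531; adjusted p = 0.195 with an estimated correlation), and the list lost its call over genes above 16 on all 4 arrays (camera adjusted p = 0.128). The collagen cross-linking enzyme gene LOX, not above 16 in cells alone, was at least 7.74-fold higher, and the urokinase receptor gene PLAUR rose 4.22-fold (2.08 ± 0.10, SE). Fibroblast markers that were not above 16 in cells alone moved with this list, DCN by a log2 change of at least 3.09, COL1A2 by at least 1.27 and PDGFRB by at least 1.14. Of 12 tested epithelial genes, 8 were lower and 2 higher (9 lower adjusted over the list alone), with a median log2 change of -0.39 (camera adjusted p = 0.0129; adjusted p = 0.215 with an estimated correlation), and the list missed the threshold at a floor of 32 and over genes above 16 on all 4 arrays. The E-cadherin gene CDH1 was 1.92-fold lower, with 1 of the 2 co-culture arrays under 16, and the tight junction gene CLDN7 was 2.18-fold lower.

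ER chaperone, NRF2, heat shock and insulin-responsive lists did not shift by camera with the filter on dim probes. Among 16 tested ER chaperone genes, 4 were higher and 1 lower (adjusted p = 0.287), among them SDF2L1 at 1.49-fold and HSP90B1 at 1.46-fold higher. Among 18 tested NRF2 and oxidative stress genes, 3 were higher and 9 lower (adjusted p = 0.287 by camera and 0.0328 by fry). Of these, the drug exporter gene ABCC3 was 2.26-fold lower and PIR 1.79-fold lower. Among 17 tested heat shock genes, 4 were higher and 3 lower (adjusted p = 0.223; 0.0140 with no filter), with the small heat shock protein genes CRYAB 2.52-fold and HSPB1 1.58-fold lower. Adjusted over the list alone, 5 heat shock genes were higher, and the counts of the other lists named here did not differ. Among 11 tested insulin and FOXO responsive genes, 5 were higher and 4 lower (adjusted p = 0.791), and the median (-0.20) and mean (0.08) differ in sign. In this list IGFBP1 was at least 3.46-fold higher and KLHL24 2.35-fold lower.

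Fibroblast markers rose in part. Of 8 tested fibroblast and preadipocyte markers, 5 were higher, 1 was lower and 2 did not pass (6 higher and 2 lower adjusted over the list alone). Their median log2 change was 0.88 (camera adjusted p = 0.0254; adjusted p = 0.244 with an estimated correlation). The matrix proteoglycan gene DCN was at least 8.53-fold higher in co-culture, COL1A2 at least 2.41-fold and PDGFRB at least 2.21-fold. The other DCN probes lay under 16 on every array. Their means were 8.95, 6.6 and -0.95 in co-culture against 0.8, -0.3 and 4.8 in cells alone. COL1A1 was 1.97-fold and LUM 1.72-fold higher, the latter above 16 on 1 of the 2 arrays of cells alone. The other LUM probe read under 16 on every array. FBLN1 was 1.31-fold lower, but its probe ILMN_1672536 rose, from 351 and 337 in cells alone to 381 and 389 in co-culture. With the mean of the kept probes, the log2 change of FBLN1 was -0.12 (limma adjusted p = 0.288). This list lost its call without replicate 1 of cells alone (camera adjusted p = 0.0753), without replicate 2 of cells alone (0.0677) and with a floor of 32 (0.411), and over the members above 16 on all 4 arrays its median log2 change was -0.27 (camera adjusted p = 0.716).

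Adipocyte markers other than FABP4 and CD36 were mostly below the filter. Of the 5 tested members, CFD was 1.43-fold higher, CEBPA 1.30-fold lower, and 3 did not pass (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.924). Among 3 tested lymphocyte markers, CCL5 was at least 2.30-fold higher and CD52 2.07-fold lower (camera adjusted p = 0.558), with 2 higher adjusted over the list alone. Among 4 tested mesothelial markers, LRRN4 was at least 1.90-fold and ITLN1 at least 1.43-fold higher, UPK3B at least 3.66-fold lower and MSLN 1.71-fold lower (camera adjusted p = 0.892), and the counts of this and the macrophage list did not differ adjusted over the list alone. No endothelial or red cell marker passed the filter. The calls of FBLN1, CEBPA, LUM, CCL5 and PDGFRB were each lost under at least 1 setting that kept all 4 arrays and a filter.

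**Figure D3:**
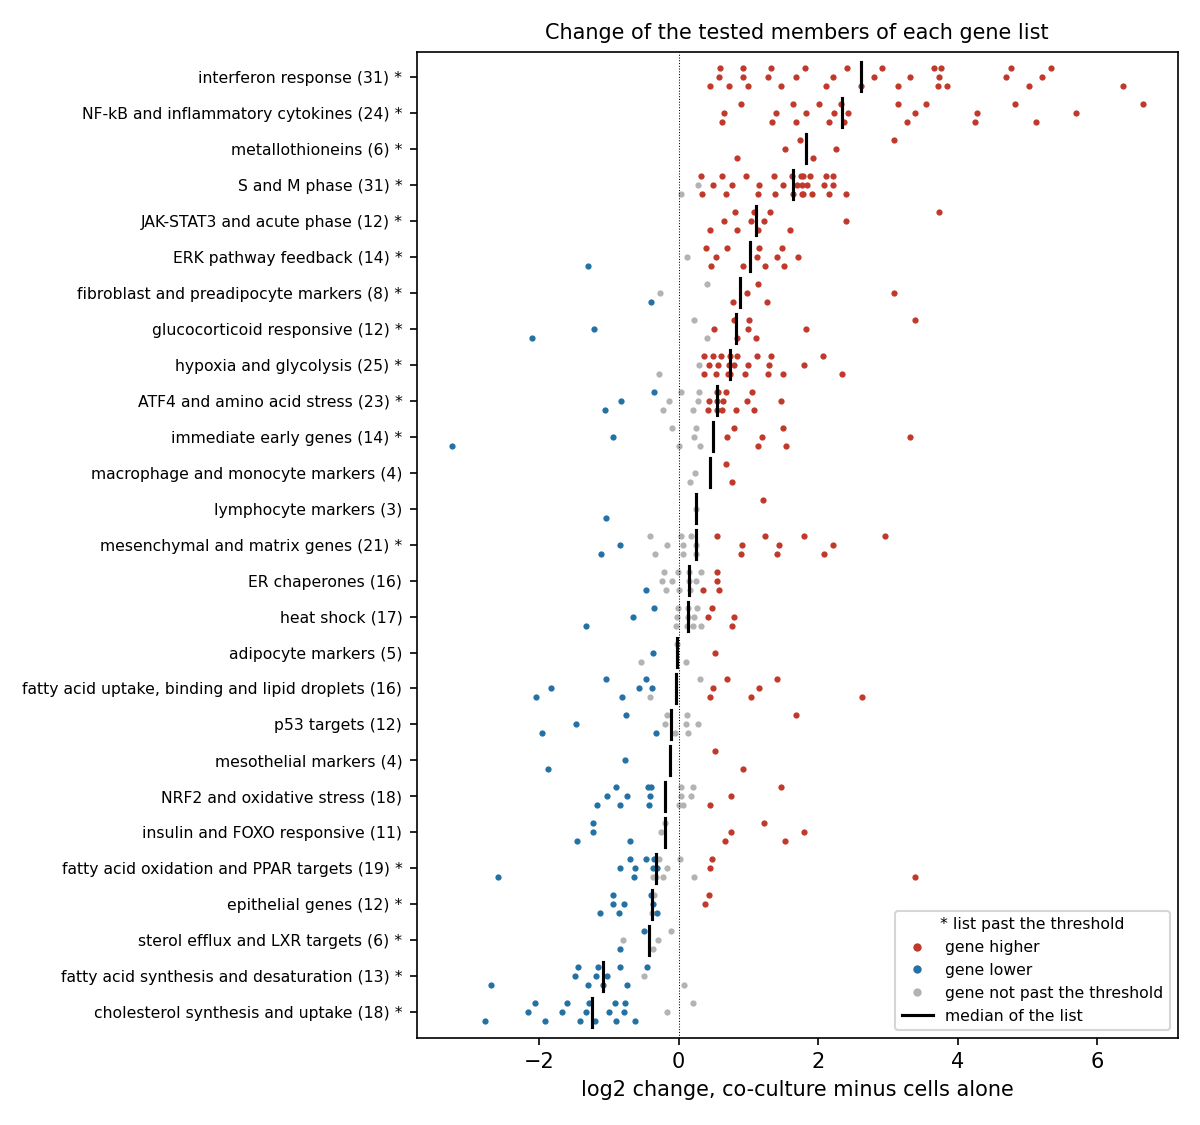
Log2 change (co-culture minus cells alone) of every tested member of the 27 gene lists with at least 3 tested genes, a point per gene coloured by its own test, with a bar at the list's median and the number of tested members in brackets. Lists with an asterisk passed camera with a preset correlation of 0.01, and their medians run from -1.24 for cholesterol synthesis and uptake to 2.62 for the interferon response.

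Of the 27 lists, 17 shifted by camera (12 up and 5 down) and 20 moved by fry, which does not compare a list with other genes. With an inter-gene correlation estimated from the data none of the 27 passed after adjustment, and 6 had an unadjusted p under 0.05. This form of camera rests on 2 residual degrees of freedom here, so it had little power. Whether correlation between genes explains the shifts stays open.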

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

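Of the tests in this part, those of adipocyte RNA, of all transcripts at or under 16 in cells alone and of LXR targets were chosen only after the result was seen. Probes that the annotation given with the data does not name lie outside the comparisons of genes, and they carried a signal. Of 2516 such probes tested, 322 were higher and 465 lower in co-culture, against cells alone as the control. The probe ILMN_2150851 had the largest rise against the floor of 16 (log2 change of at least 5.43, not above 16 in cells alone), and ILMN_3243598 the largest fall (by at least 3.09, not above 16 in co-culture).

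The interferon response list rose in co-culture, with a median log2 change of 2.62 over 31 genes, a shift that did not pass with an estimated correlation (camera adjusted p = 0.136). Carried-over leukocytes are a technical candidate explanation: 2 of 16 abundant leukocyte transcripts (SRGN and ITGB2) were above 16 on both co-culture arrays and higher, 14 were at or under 16 on both, and the 15 at or under 16 in cells alone had a median rise of 1.55 units, inside the central 95% of random lists (-1.95 to 2.50), which argues against leukocytes in general as the source of the whole rise. Macrophage markers went the other way, since CD14 and CD68 were higher, the 10 markers at or under 16 in cells alone had a median rise of 4.23 units against -2.28 to 2.92, and their list passed by fry (adjusted p = 0.0265), with all probes (0.0150) and with a floor of 8 (0.0411), within a range of 0.0150 to 0.287 over 17 settings, so a contribution of macrophage RNA stays open. The list's median of 2.62 was set against 10000 random lists matched on mean intensity, whose central 95% ran from -0.22 to 0.17. Genes of like intensity did not share the shift. This repeats the comparison with other genes that had flagged the list, so it is no separate test of array-wide normalization. A response of the cancer cells to the adipocytes, or to cells that came with them, stays open as a hypothesis, and other causes that go with the co-culture dish, such as handling, were not tested.

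The cholesterol and fatty acid synthesis lists fell, a shift that did not pass with an estimated correlation (camera adjusted p = 0.174 for both). The median log2 change of both lists together was -1.16, outside the central 95% of random lists matched on mean intensity (-0.20 to 0.15). As above, this repeats the comparison with other genes and is no separate test of array-wide normalization. Sterol loading of a kind that activates LXR would raise its targets, and 0 of 6 tested targets were higher while ABCA1 was lower. Induction of CH25H, whose product 25-hydroxycholesterol shuts off sterol synthesis genes, cannot be told apart from other causes: its probe read at most 2.5 in co-culture, and a transcript near the floor at 16 h excludes neither an earlier nor a low expression, although the test had been written to count such a reading against it. Uptake of fatty acids or sterols from the adipocytes stays among the open explanations, as untested.

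Fibroblast markers rose in co-culture, led by DCN on 1 of its probes, a shift that did not pass with an estimated correlation (camera adjusted p = 0.244). RNA of a small share of carried-over adipocytes cannot be told apart from other causes: 1 of 19 adipocyte transcripts (CFD, which the cells alone also express) was above 16 on both co-culture arrays and higher, and the 12 markers at or under 16 in cells alone had a median rise of 0.90 units, inside the range of random lists (-2.02 to 2.70), but FABP4 read 12.8 and 13.9 in co-culture against 3.9 and 2.6, and a rise that stays under 16 is not counted. For carried-over stromal cells, 3 of 20 transcripts of a second stromal list were above 16 and higher (MGP, COL6A3 and BGN), and the test had been written to count so few against this explanation, but 11 of the 20 were at or under 16 on both co-culture arrays, where it counts no rise, and 5 were above 16 in cells alone, where a small share adds little. Over the 15 members at or under 16 in cells alone, 12 rose and the median rise was 5.75 units, above the central 95% of 10000 random lists of such transcripts (-1.95 to 2.50), which is consistent with a small share of stromal RNA. Induction of these genes in the cancer cells stays open as well, and whether any of the 169 higher genes that were not above 16 in cells alone, IL6 among them, came from carried-over cells was not tested.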

How the results depend on the processing

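Floors of 8 and 32, the filter on all 4 arrays and log2 of intensity plus 50 were chosen after the data were seen. The floor of 16 and the intensity filter of the main fit were not in the fixed design either. Every setting that kept all 4 arrays and used a filter left between 3229 and 5170 features called by adjusted p alone, of which between 2937 and 3653 were among the 3827 genes, and 15 were called the other way, all with each probe tested singly. A minimum of 2-fold left 856 genes (477 higher, 379 lower). With no filter 641 genes were called (343 higher, 298 lower), of which 614 were among the 3827; many genes then have no spread at the floor, and the prior degrees of freedom fell to 0.253. The 3827 genes kept their direction with each array left out in turn, as they had to, since their groups did not overlap. In these fits every limma call was lost. The lowest adjusted p then lay between 0.058 and 0.0603, and the residual degrees of freedom were fewer, with the lone array of a group assumed to vary like the pair of the other. With log2 of intensity plus 50 and each array left out, genes were still called, but their errors rested mostly or wholly on the prior. The prior degrees of freedom were then infinite without an array of cells alone and 9.82 without an array of co-culture. Same-numbered arrays of the groups did not deviate together (correlation across genes -0.034), so the numbers are not taken to pair the arrays. The fit with the replicate block called 3395 genes (1587 higher, 1808 lower), of which 3281 were among the 3827. The list count of 17 went to 0 with an estimated correlation, to 12 over genes above 16 on all 4 arrays, to 13 with a floor of 32, and to 15 to 16 with each array left out. Of the 17 shifted lists, 12 passed under 18 of 19 other settings, all but the estimated correlation, the fatty acid oxidation list under 7 and the sterol efflux list under 8. Of single lists, 44 results over all settings lost the threshold, 6 gained it, and the fibroblast markers reversed over genes above 16 on all 4 arrays (median log2 change -0.27, adjusted p = 0.716, against 0.00501 to 0.716 over its 19 other settings), where members not above 16 in cells alone drop out. Of the named genes, 814 results kept direction and side of the threshold, 316 lost it (272 with an array left out, 31 with no filter) and 0 reversed. The planned settings without background correction, with a neqc offset of 50 or with median scaling were not run. Nor were those with detection p on 4 arrays or under 0.05. The reason is that no column name of the unnormalized table matches a sample. A slide block was not run. Intensity over background limits genes near the floor: below 16 no fold can be given, as for FABP4, which with a floor of 8 was higher by a log2 change of at least 0.74 (adjusted p = 0.0113) and with no filter lay at the floor on every array.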

Other observations

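The lists and families in this part were all chosen after the data were seen, and their members overlap in part with the lists of the report. Genes of HLA class I molecules and of antigen loading rose in co-culture: of 12 tested genes, 11 were higher. Among them were the peptide transporter genes TAP1 (log2 change 1.32 ± 0.09, SE) and TAP2 (1.76 ± 0.14), HLA-B (1.56 ± 0.13) and B2M, the light chain of class I molecules (0.65 ± 0.09). The camera adjusted p over 5 such lists was 1.54e-05, and it was 0.116 with an estimated correlation. HLA genes are near-identical in part, so that a probe can read more than 1 of them. Of 10 tested genes whose symbols start with HLA, 5 were higher and 2 lower, and this family did not shift (camera adjusted p = 0.299). Of 12 tested S100 proteins and antimicrobial peptides, 7 were higher and 1 lower (camera adjusted p = 0.00471; adjusted p = 0.116 with an estimated correlation). The protease inhibitor gene PI3 (elafin) was not above 16 in cells alone and rose by a log2 change of at least 4.12, S100P by at least 3.30, and SLPI, another antimicrobial protease inhibitor gene, by 2.59 ± 0.09. None of the 10 interferon genes looked up read above 16 in co-culture: IFNE read at most 14.3 there (33.9 in cells alone), IFNA1 10.0, IFNW1 8.6 and IFNA2 4.3, and IFNB1, IFNG, IFNK, IFNL1, IFNL2 and IFNL3 at most 1.9.

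Lysosomal genes fell in part: of 29 tested, 15 were lower and 3 higher (camera adjusted p = 0.00382; adjusted p = 0.116 with an estimated correlation), with the sialidase gene NEU1 lower (log2 change -2.05 ± 0.10) and the cysteine protease genes CTSL (0.87 ± 0.09) and CTSB (0.61 ± 0.13) higher. Of 20 tested ribosome biogenesis genes, 7 were higher and none lower (camera adjusted p = 2.97e-04; adjusted p = 0.116 with an estimated correlation). Among 102 families of genes that share the start of their symbol, with at least 10 tested genes each, 4 shifted by camera and none with an estimated correlation (adjusted p = 0.728 for these 4). Nucleoporin genes (symbols starting with NUP) were higher for 15 of 21 members (camera adjusted p = 3.61e-04), kinesin genes for 13 of 22 with 5 lower (adjusted p = 0.0357), while aldehyde dehydrogenase genes were lower for 9 of 15 with 1 higher (adjusted p = 0.0357) and protocadherin beta genes for 6 of 11 (adjusted p = 0.0440). Markers at or under 16 in cells alone were compared with 10000 random lists of such transcripts: 10 macrophage and monocyte markers had a median rise of 4.23 intensity units (central 95% of random lists from -2.28 to 2.92) and 7 fibroblast and preadipocyte markers one of 21.9 (from -2.85 to 3.50), while adipocyte, lymphocyte, endothelial, mesothelial and red cell markers lay inside the range of their random lists.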
